A study of Danio rerio with 24 samples.

How the data were processed

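Whole zebrafish embryos of 2 genotypes, wild type and maternal eevs mutants (Meevs), were mock treated or exposed to 450 J of UVB at 24 hpf and collected 5 h or 24 h later. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a directional polyA kit. The 8 groups hold 3 libraries each, 24 in all. The unit of the dose is given in the labels as J, with no area. The descriptions name 1 library series for all wild type libraries and another for all Meevs libraries, so genotype and series cannot be separated.

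The deposited table holds read counts per gene, as whole numbers that were not normalized by the authors. Per the submitters' processing notes, the tools were cutadapt 1.16, STAR 2.7.9a, featureCounts 1.6.3 and DESeq2 1.36.0, and the genome build was GRCz11; their settings and order are not given in the sources used here. The kit keeps the strand, but whether the counting used it is not given in the sources used here, so overlapping antisense genes are uncertain. The smallest total of any gene over the 24 libraries was 19 counts. The authors also deposited 12 tables of comparisons between groups, which per the file headers hold a log2 fold change and an adjusted p-value from DESeq2 for each gene. These were used only to count calls: in the authors' deposited table for wild type at 5 h 1580 genes were higher and 1581 lower at an adjusted p under 0.05, and 97.78% of the genes called here were called there in the same direction. In the authors' deposited table for wild type at 24 h the counts were 371 and 235, and 92.42% of the calls made here were shared. The authors' deposited table for Meevs at 5 h gave 4344 and 3465 with 98.36% shared, and the authors' deposited table for Meevs at 24 h gave 2373 and 2448 with 94.64% shared.

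Each column of counts was assigned to its library by the name in the labels. Gene symbols, chromosomes, starts and ends were taken from the count table, and 21809 of its 23219 gene identifiers were also found in the reference table of gene names. Of the genes in the table, 393 repeat the symbol of another identifier and 69 have no symbol. No genome sequence and no transcript lengths were used here, so gene span, from start to end, stood for gene length.

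Total counts per library lay between 22395870 and 44691629. The 50 most abundant genes held between 17.5% and 22.8% of a library, and mitochondrially encoded genes between 2.03% and 2.96%. Replicates of each group were compared by a chi-square of their counts over genes with a mean of at least 10 counts. The chi-square per degree of freedom lay between 4.28 and 23.2, so no 2 libraries agreed within sampling noise and each was counted as 1 replicate.

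The main test was fixed before the data were examined. Counts were scaled with TMM, genes with low counts were removed with filterByExpr by group (22340 genes stayed), and a model with 1 mean per group was fitted to all 24 libraries with edgeR 4.0.16 in R 4.3.3, so that all groups share 1 estimate of the spread. Contrasts were tested with the quasi-likelihood F-test, p-values were adjusted by Benjamini-Hochberg over all tested genes of a contrast, and genes with an adjusted p under 0.05 were called. The 14 contrasts were the UVB effect in each genotype and time, the difference of these effects between genotypes and between times, the genotype effect in mock and in UVB embryos, and the time effect in mock embryos. The SE of a log2 fold change is its size divided by the square root of F. CPM use TMM-scaled library sizes, and principal components were computed on log2 CPM with a prior count of 2.

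In addition, 35 gene lists with 1244 members in all were fixed before the data were examined, of which 1131 matched a symbol of the table. They were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a contrast. As an alternative the correlation was estimated from the data, which left 43 of 196 list calls and ended 153. For each list the calls were also counted with p-values adjusted over the list alone.

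Genes named in the text were chosen by a rule fixed before the data were examined. They had to be called, have a mean of at least 1 log2 CPM over the 24 libraries, have libraries of the compared groups that do not overlap (a share of 10% of genes does so by chance with 3 against 3; this condition was not used for interactions), and have a symbol that is not a clone or locus placeholder. The 10 highest and 10 lowest were named for the UVB effects and the genotype effects in mock embryos, and the 5 highest and lowest for the other contrasts. The gadusol genes and up to 4 members per list with the smallest adjusted p were named as well. Placeholder symbols made up between 4 and 13 of the 20 largest changes of a contrast. Members of small counts, the genes drawn per library, genes of opposite calls and the rising long genes were named after their values were seen. Some genes that met this rule and some of the lists are not reported here.

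The tests were checked on simulated counts drawn from the means, totals and spread of the real libraries, with 200 of 22340 genes changed. The changed genes were drawn only from genes of higher mean counts, so genes read at few counts are not covered. Every real contrast called more genes than were changed here, so the shares may not carry over to the real contrasts. For the wild type UVB effect at 5 h, 74% of genes changed 1.5-fold were recovered, 94% at 2-fold and 100% at 4-fold and at 8-fold, with 4.66% false calls. For the genotype-by-UVB difference at 5 h the shares were 42%, 80%, 96% and 98%, with 8.14% false calls, which is above the 5% that the threshold aims at. A list raised 1.5-fold was called, and 1 of the other 34 lists was called too. Each gene was drawn on its own, so this check does not cover false calls of lists whose members move together.

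Alternatives fixed beforehand were DESeq2 size factors (RLE) within edgeR, the DESeq2 1.42.0 Wald test, no filter on low counts, a fit of the compared groups only, a replicate block, an estimated inter-gene correlation, and leaving out each replicate in turn. A per-library offset for gene span (lowess with a span of 0.3), leaving out the 2 libraries at 5 h that stood apart on the principal components, and thinning all libraries to the smallest total were added after seeing the data. For splits of the libraries into other groups, each model was fitted to the compared libraries only, over all 10 splits of 6 libraries or 100 drawn splits of 12.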

Results

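Whole zebrafish embryos were profiled by polyA-selected, strand-specific RNA sequencing to compare the response to ultraviolet B (UVB) of wild type embryos with that of maternal eevs mutants (Meevs). The gene eevs encodes the enzyme that starts the synthesis of gadusol, a sunscreen compound of fish that absorbs UVB. At 24 h post fertilisation (hpf) embryos received 450 J of UVB or a mock exposure. They were kept in the dark until collection 5 h later (29 hpf) or 24 h later (48 hpf). The 2 genotypes, 2 treatments and 2 times made 8 groups of 3 libraries, 24 in all. Total counts per library lay between 22395870 and 44691629, and 22340 of 23219 genes had enough counts to be tested. The labels do not say whether replicates came from separate clutches, so p-values measure only the spread between these samples, which may be technical. Log2 fold changes are given ± SE from the edgeR fit of all 24 libraries, levels as CPM (counts scaled to library size) ± SD with n = 3, and adjusted p is Benjamini-Hochberg adjusted. Genes called largest, highest, lowest or leading are ranked among called genes with a mean of at least 1 log2 CPM and an established symbol. For a gene list, counts adjusted over the list alone are given with the higher members first and the lower ones after them. Some genes belong to more than 1 list, such as mmp9 to inflammation and to wound and fin regeneration, so list calls are not independent.

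The first principal component of log2 CPM held 58.98% of the variance and ordered the libraries by time. The second held 17.96% and ordered them by genotype, with which the library series named in the descriptions coincides. Components 3 and 4 held 4.34% and 3.89% and separated UVB from mock libraries within each genotype and time. Of the libraries, 4 lay furthest from the other replicates of their groups on components 1 and 2. At 5 h these were replicate 3 of Meevs mock, at 51.6 on component 2 against 18.8 and 24.2 for the other replicates, and replicate 3 of wild type UVB, at -69.7 on component 1 against -88 and -82.5. At 24 h they were replicate 1 of wild type UVB, at 84.8 on component 1 against 65.5 and 69.5, and replicate 3 of Meevs UVB, at 39.3 on component 2 against 54.5 and 61.7.

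**Figure D1:**
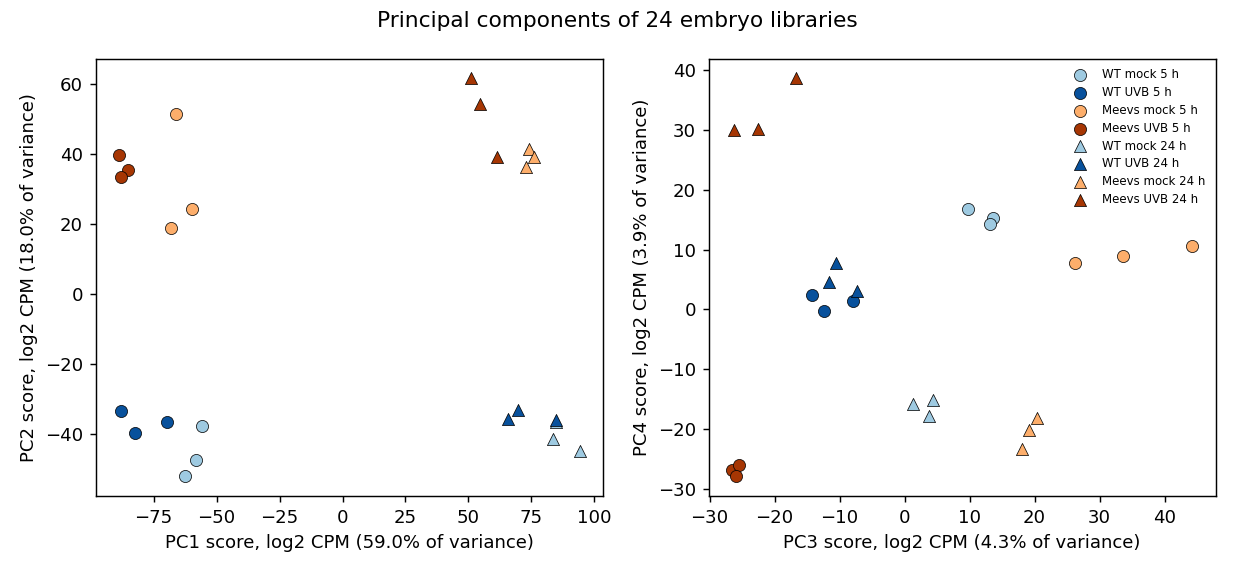
Principal components 1 to 4 of log2 CPM over the 22340 tested genes, 1 point per library, with groups marked by genotype, treatment and time. Component 1 (58.98% of the variance) orders the libraries by time and component 2 (17.96%) by genotype.

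The targeted gene, eevs (ENSDARG00000087873, chromosome 6, 43438074 to 43449013, GRCz11), was read at low counts, between 2 and 84 per library. In wild type its level was 0.216 ± 0.0355 CPM in mock and 0.289 ± 0.0753 CPM in UVB embryos at 5 h. At 24 h it was 0.712 ± 0.0759 and 0.403 ± 0.0793 CPM. In Meevs it was 0.211 ± 0.102 CPM in mock and 2.22 ± 0.276 CPM in UVB embryos at 5 h, then 2.53 ± 0.885 and 0.663 ± 0.158 CPM at 24 h. Against wild type, the log2 difference of eevs in Meevs mock embryos was -0.02 ± 0.52 at 5 h (edgeR adjusted p = 0.982) and 1.80 ± 0.26 at 24 h (edgeR adjusted p = 3.34e-06). A maternal mutant label names the mother's genotype, and the labels give neither the lesion nor the embryos' own alleles, so this level checks no label. Within Meevs, eevs rose with UVB at 5 h (3.34 ± 0.36, edgeR adjusted p = 3.73e-08) and fell at 24 h (-1.90 ± 0.28, edgeR adjusted p = 1.25e-05). In wild type neither change passed (edgeR adjusted p = 0.571 and 0.237). The difference between the genotypes' UVB effects passed at 5 h (2.90 ± 0.61, edgeR adjusted p = 0.0046) and did not at 24 h (-1.09 ± 0.44, edgeR adjusted p = 0.246). The neighbouring zgc:113054 (ENSDARG00000053483, chromosome 6, 43450221 to 43474757) encodes the second enzyme of gadusol synthesis. Its level was 16.7 ± 1.05 CPM in wild type and 22.7 ± 1.18 CPM in Meevs mock embryos at 5 h. It differed between the genotypes by 0.44 ± 0.10 in mock embryos at 5 h (edgeR adjusted p = 0.000629). In Meevs it rose with UVB at 5 h (0.33 ± 0.10) and fell at 24 h (-0.59 ± 0.10). Of the 9 measured members of the list for gadusol synthesis and its locus, 4 (zgc:113054, uba3, lmod3 and eevs) rose with UVB in Meevs at 5 h and the other 5 did not pass in edgeR. Its test passed with neither correlation (4 and 0 adjusted over the list alone, camera adjusted p = 0.256, adjusted p = 0.554 with an estimated correlation).

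**Figure D2:**
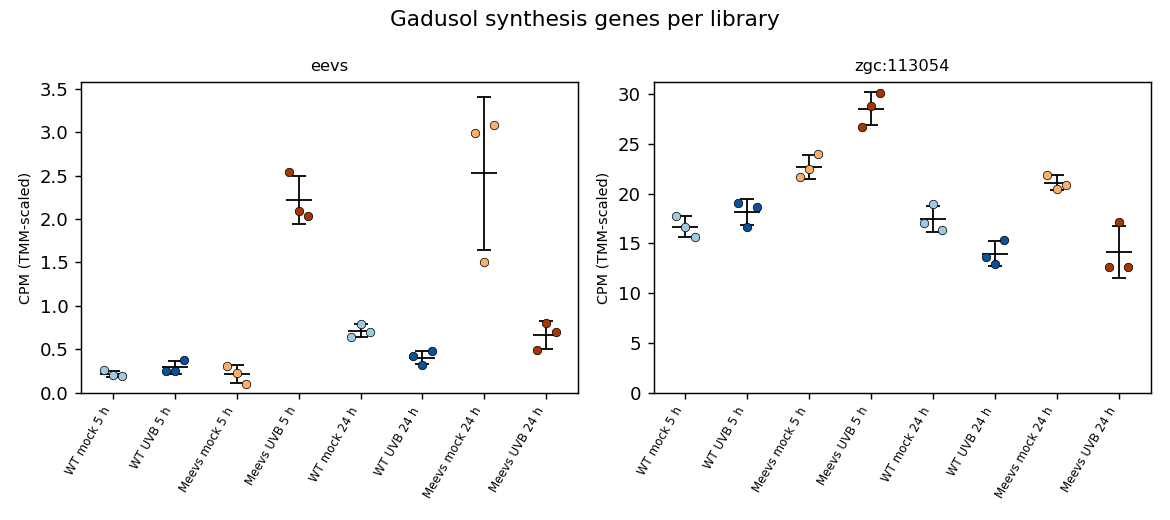
CPM of eevs (left) and of zgc:113054 (right) in each of the 24 libraries, with bars at group means and error bars of 1 SD (n = 3). The Meevs UVB libraries at 5 h and the Meevs mock libraries at 24 h hold the 2 highest group means of eevs, 2.22 and 2.53 CPM.

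The first comparison asked what UVB changed in wild type embryos after 5 h. The gene cdkn1a (ENSDARG00000076554, chromosome 22, 603382 to 607812), the p21 inhibitor of the cell cycle, went from 3.70 ± 0.469 to 23.5 ± 0.190 CPM. Its log2 fold change was 2.67 ± 0.16 (edgeR adjusted p = 2.15e-11). The DNA damage gene gadd45aa rose by 2.1 ± 0.13, and isg15, a ubiquitin-like interferon-stimulated gene on chromosome 5 (20112032 to 20113284), by 2.64 ± 0.32. Among the other genes with the largest rises were fosab (1.96 ± 0.22) and fosl1a (1.62 ± 0.21), which encode AP-1 subunits, and cyp24a1 (1.69 ± 0.23), the vitamin D hydroxylase. Rises followed in irg1l (1.35 ± 0.32), c7b (1.25 ± 0.31), phlda3 (1.2 ± 0.12) and slc25a38a (1.159 ± 0.22). The largest falls were in slc12a10.2 (-2.40 ± 0.40, chromosome 7, 4332430 to 4380448), a sodium-chloride cotransporter of ionocytes, and cemip (-1.91 ± 0.18), a hyaluronan-degrading protein. Genes of the extracellular matrix and of cell adhesion followed, gpc5a (-1.54 ± 0.16), adamts2 (-1.44 ± 0.18), col17a1a (-1.33 ± 0.18), cdh26.2 (-1.29 ± 0.21), paplna (-1.27 ± 0.21) and col5a2b (-1.23 ± 0.31). Also lower were the peptide gene grp (-1.53 ± 0.21) and the transcobalamin gene tcnbb (-1.42 ± 0.21).

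In all, 1489 genes rose and 1353 fell in wild type at 5 h, of which 78 and 156 changed at least 2-fold. Of the 21 ionocyte and mucous cell markers 9 fell and none rose (0 and 11 adjusted over the list alone, camera adjusted p = 2.55e-12, adjusted p = 0.0146 with an estimated correlation). Among them were atp1a1a.2 (-0.94 ± 0.09), ceacam1 (-1.02 ± 0.12) and ca15a (-0.77 ± 0.10). Keratinocyte and periderm markers fell in 22 of 47 cases and rose in 1 (cldna). The counts became 2 and 24 adjusted over the list alone (camera adjusted p = 1.52e-14, adjusted p = 0.121 with an estimated correlation). Members included agr2 (-0.79 ± 0.10), evpla (-0.78 ± 0.10) and ppl (-0.62 ± 0.09). Heat shock proteins rose in 8 of 28 cases (14 and 0 adjusted over the list alone, camera adjusted p = 1.4e-09, adjusted p = 0.121 with an estimated correlation). Such genes were hspa4a (0.64 ± 0.10) and hsp90aa1.2 (0.66 ± 0.11). Immediate early genes rose in 11 of 29 cases and fell in 1 (klf2b). These were 12 and 1 adjusted over the list alone (camera adjusted p = 2.55e-05, adjusted p = 0.122 with an estimated correlation). Extracellular matrix and cartilage genes fell in 13 of 44 cases (0 and 13 adjusted over the list alone, camera adjusted p = 1.09e-05, adjusted p = 0.369 with an estimated correlation). Pigment cell markers fell in 7 of 33 cases and rose in 1 (gmps). The counts became 1 and 11 adjusted over the list alone (camera adjusted p = 0.000354, adjusted p = 0.533 with an estimated correlation). Of 20 interferon-stimulated genes 1 rose and 2 fell, and the list's test did not pass (2 and 3 adjusted over the list alone, camera adjusted p = 0.904, adjusted p = 0.929 with an estimated correlation). The count of 2842 genes became 1781 without replicate 3 of the mock group and 1385 without replicate 1 of the UVB group. It became 1768 (754 higher, 1014 lower) when only these 6 libraries were fitted.

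After 24 h, inflammatory, complement and hatching gland genes were among the largest rises in wild type embryos. The largest rise was in he1.3 (ENSDARG00000022670, chromosome 22, 14102397 to 14103633), a hatching enzyme gene, at 4.62 ± 0.45 (edgeR adjusted p = 1.59e-07). Its level went from 0.0798 ± 0.0477 CPM (1 to 4 counts per library) to 2.07 ± 0.279 CPM, and ctslb, a cathepsin of the hatching gland, rose by 2.49 ± 0.33. The complement genes c3a.3 (chromosome 1, 56274613 to 56320569) and c6 rose by 2.73 ± 0.21 and 2.76 ± 0.24. The symbols ctslb and c6 are each given to more than 1 gene identifier. The matrix metalloproteinase gene mmp9 went from 4.11 ± 0.429 to 18.4 ± 2.86 CPM (2.16 ± 0.14), and socs3a, a feedback inhibitor of JAK-STAT signalling, rose by 1.79 ± 0.14. Genes high at 5 h were still raised, namely cdkn1a (2.02 ± 0.18), fosl1a (2.12 ± 0.24), irg1l (2.15 ± 0.20) and isg15 (1.83 ± 0.26). The largest falls were in rho (-1.27 ± 0.26), the rod opsin, muc5.2 (-1.21 ± 0.19), a mucin, and matn1 (-1.21 ± 0.28), a cartilage matrilin. Falls followed in ponzr4 (-1.18 ± 0.28), ponzr3 (-1.12 ± 0.28), gnb3a (-1.07 ± 0.27), slc12a10.2 (-0.99 ± 0.20), caspb (-0.98 ± 0.08), clcn2c (-0.92 ± 0.18) and aep1 (-0.87 ± 0.12).

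In all 388 genes rose and 113 fell, 98 and 24 of them at least 2-fold. Inflammation genes rose in 16 of 40 cases and none fell (25 and 1 adjusted over the list alone, camera adjusted p = 2.65e-32, adjusted p = 9.64e-06 with an estimated correlation). Wound and fin regeneration genes rose in 10 of 30 (17 and 0 adjusted over the list alone, camera adjusted p = 1.29e-26, adjusted p = 9.64e-06 with an estimated correlation). Examples were anxa2a (0.78 ± 0.07) and fn1b (1.5 ± 0.15). Immediate early genes rose in 12 of 29 cases (14 and 0 adjusted over the list alone, camera adjusted p = 4.21e-24, adjusted p = 0.000246 with an estimated correlation). Interferon-stimulated genes rose in 4 (irf9, irf1b, b2m and isg15) of 20 (5 and 0 adjusted over the list alone, camera adjusted p = 7.3e-05, adjusted p = 0.0144 with an estimated correlation). Ionocyte and mucous cell markers fell in 9 of 21 cases (1 and 11 adjusted over the list alone, camera adjusted p = 7.24e-12, adjusted p = 0.00958 with an estimated correlation). Notochord and hatching gland genes rose in 4 (he1.3, ctslb, tbxta and cav1) of 23 cases (6 and 1 adjusted over the list alone, camera adjusted p = 1.25e-06, adjusted p = 0.0186 with an estimated correlation). Keratinocyte and periderm markers went both ways, with krt17 at 1.31 ± 0.13. Of 47, 10 rose and 3 (col17a1a, krtt1c19e and cyt1) fell (15 and 8 adjusted over the list alone, camera adjusted p = 2.03e-06, adjusted p = 0.268 with an estimated correlation). Macrophage and neutrophil markers rose in 3 of 25 cases, mpx (0.59 ± 0.12), nccrp1 (0.33 ± 0.07) and ptprc (0.74 ± 0.17). These were 7 and 0 adjusted over the list alone (camera adjusted p = 1.25e-06, adjusted p = 0.0674 with an estimated correlation). The split of calls moved with the scaling, to 309 higher and 153 lower with DESeq2 size factors in edgeR and to 371 and 235 in DESeq2. The total of 501 became 273 without mock replicate 1, 333 without mock replicate 3, 293 without UVB replicate 2 and 313 without UVB replicate 3.

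In Meevs embryos at 5 h the same question was asked of the mutant. The leading genes were again isg15 (4.99 ± 0.24, edgeR adjusted p = 1.2e-14) and cdkn1a (3.94 ± 0.16), the latter going from 3.43 ± 0.507 to 52.9 ± 4.18 CPM. They were followed by fosab (3.87 ± 0.21), gadd45aa (3.43 ± 0.13) and fosl1a (3.08 ± 0.22). The gene cry5, which encodes a photolyase that repairs 6-4 photoproducts, went from 6.26 ± 1.01 to 36.9 ± 1.47 CPM (2.56 ± 0.14). Also among the largest rises were ptgdsb.2 (3.31 ± 0.27) and ptgdsb.1 (2.41 ± 0.12), neighbouring prostaglandin D synthase copies between which reads could be shared. The others were nfil3-6 (2.99 ± 0.24) and crtac1a (2.67 ± 0.17). Among the largest falls were those of NPAS3 (-3.64 ± 0.38, chromosome 17, 9308425 to 9894157), a neuronal transcription factor gene, and of klhl29 (-3.15 ± 0.22), cemip (-2.98 ± 0.22) and ptprua (-2.93 ± 0.17). Next came clstn2 (-2.85 ± 0.36), slc12a10.2 (-2.71 ± 0.43), trappc9 (-2.71 ± 0.21), cntn5 (-2.67 ± 0.24) and sdk1a (-2.57 ± 0.21).

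In all 4256 genes rose and 3419 fell, 311 and 840 at least 2-fold. Photolyase and circadian clock genes rose in 16 of 41 cases and fell in 5 (bhlhe40, per1b, rorcb, roraa and per1a). The counts became 20 and 5 adjusted over the list alone (camera adjusted p = 4.85e-08, adjusted p = 0.0108 with an estimated correlation). Among them were cry3b (1.75 ± 0.08), cry-dash (1.72 ± 0.09) and tefa (1.25 ± 0.07). Ionocyte and mucous cell markers fell in 12 of 21 cases (0 and 12 adjusted over the list alone, camera adjusted p = 1.13e-08, adjusted p = 0.0352 with an estimated correlation). Nucleotide excision repair genes rose in 11 of 33 cases and fell in 1 (uvssa). These were 11 and 1 adjusted over the list alone (camera adjusted p = 0.0105, adjusted p = 0.612 with an estimated correlation). Leading were the damage sensors ddb2 (2.2 ± 0.13) and xpc (0.83 ± 0.08). Keratinocyte and periderm markers fell in 33 of 47 cases and rose in 4 (krt18a.1, krt94, cldna and krt96). The counts became 5 and 36 adjusted over the list alone (camera adjusted p = 6e-13, adjusted p = 0.131 with an estimated correlation). Extracellular matrix and cartilage genes fell in 20 of 44 and rose in 3 (sox9a, sp7 and acana). These were 3 and 22 adjusted over the list alone (camera adjusted p = 2.77e-08, adjusted p = 0.151 with an estimated correlation). Members included col5a1 (-1.22 ± 0.09), and2 (-1.64 ± 0.14) and and3 (-2.17 ± 0.19). Heat shock proteins rose in 14 of 28 cases (14 and 0 adjusted over the list alone, camera adjusted p = 0.000274, adjusted p = 0.494 with an estimated correlation). Immediate early genes rose in 14 of 29 and fell in 1 (klf2b). The counts became 14 and 1 adjusted over the list alone (camera adjusted p = 2.63e-06, adjusted p = 0.102 with an estimated correlation). Macrophage and neutrophil markers fell in 8 of 25 cases (0 and 8 adjusted over the list alone, camera adjusted p = 0.0129, adjusted p = 0.553 with an estimated correlation). Such genes were npsn (-1.08 ± 0.13), mpx (-0.95 ± 0.14) and lyz (-0.98 ± 0.17). Of 20 interferon-stimulated genes 5 rose and 4 fell, and the list's test did not pass (5 and 4 adjusted over the list alone, camera adjusted p = 0.305, adjusted p = 0.612 with an estimated correlation). Without the 2 libraries at 5 h that stood apart on the principal components the split was 2981 higher and 3591 lower.

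Gene span moved with the UVB effect at 5 h in both genotypes. From genes spanning up to 10 kb to those over 200 kb, the median log2 fold change went from 0.08 to -0.33 in wild type and from 0.15 to -0.82 in Meevs. Of the 472 genes over 200 kb, 160 fell in wild type and 320 in Meevs, NPAS3 among them, while in Meevs 2 rose, pcdh1b (0.26 ± 0.09) and ccnd2a (0.53 ± 0.10). At 24 h the median of this class was -0.15 in wild type and -0.19 in Meevs. Across genes, which are not independent replicates, Spearman's correlation of the log2 fold change with span was -0.285 in wild type and -0.291 in Meevs at 5 h, and -0.146 and -0.075 at 24 h. With gene length as an offset, an alternative chosen after seeing the data, the called falls of rbfox1 (-0.63 ± 0.10 in Meevs at 5 h) and rbfox3a (-0.62 ± 0.11), neuronal splicing factor genes, turned to 0.38 and 0.47. Gene lists were not tested with this offset, so the part of gene span in their changes at 5 h is not known.

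**Figure D3:**
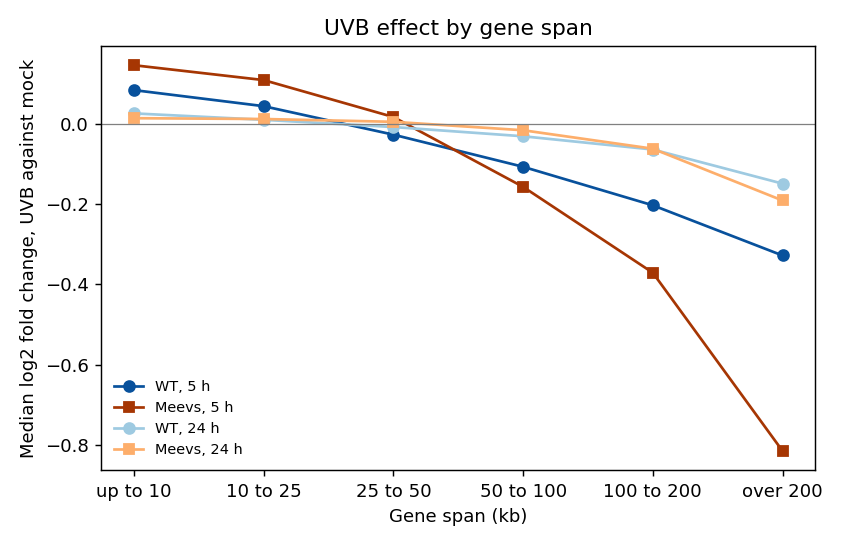
Median log2 fold change of UVB against mock in 6 classes of gene span (kb, horizontal axis), 1 line per genotype and time. At 5 h the medians of genes over 200 kb were -0.33 in wild type and -0.82 in Meevs; at 24 h they were -0.15 and -0.19.

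At 24 h the largest rise in Meevs was in the complement gene c3a.3, by 5.60 ± 0.27 (edgeR adjusted p = 1.9e-14), from 1.26 ± 0.558 to 60.2 ± 10.3 CPM. In wild type it went from 7.5 ± 2.18 to 49.7 ± 10.8 CPM, so that, as a ratio, the mock level differed more between genotypes than the UVB level. The complement genes c6 and c7b rose by 3.72 ± 0.22 and 3.60 ± 0.42, and mmp9 by 3.55 ± 0.14 (from 7.06 ± 0.221 to 82.9 ± 18.4 CPM). Also high were isg15, rising by 4.39 ± 0.22, and fosl1a by 3.72 ± 0.22. The hatching gland genes he1.3 and ctslb rose by 5.1 ± 0.42 and 4.18 ± 0.36, and cbx7a (ENSDARG00000038025, chromosome 3, 24986145 to 24994617), a Polycomb group gene, by 4.39 ± 0.20. The collagenase gene mmp13a rose by 3.82 ± 0.35, with 83.5 CPM in UVB replicate 1 against 20.9 and 22.9 CPM in replicates 2 and 3. Its symbol is given to more than 1 gene identifier. Among the largest falls were those of and3 (ENSDARG00000056873, chromosome 10, 22848556 to 22854758) and and2, which encode actinodins of the larval fin fold, by 3.34 ± 0.17 and 2.5 ± 0.14. The level of and3 went from 151 ± 20.2 to 14.9 ± 2.34 CPM. The rod opsin gene rho fell by 2.83 ± 0.30. Other falls were those of kera (-2.38 ± 0.12), matn1 (-2.34 ± 0.29), igfn1.3 (-2.33 ± 0.19), col10a1a (-2.16 ± 0.17), entpd5a (-2.13 ± 0.25), caspb (-2.03 ± 0.09) and thbs4a (-2.01 ± 0.17).

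In all 2578 genes rose and 1974 fell, 590 and 326 at least 2-fold. The larger share turned to falls with DESeq2 size factors in edgeR (2353 higher and 2395 lower), in DESeq2 (2373 and 2448) and with the length offset (2472 and 2555). Wound and fin regeneration genes rose in 19 of 30 cases (22 and 0 adjusted over the list alone, camera adjusted p = 3.24e-42, adjusted p = 5.76e-07 with an estimated correlation). Inflammation genes rose in 28 of 40 and fell in 1 (nos2b). These were 30 and 1 adjusted over the list alone (camera adjusted p = 4.53e-50, adjusted p = 6.97e-07 with an estimated correlation). Interferon-stimulated genes rose in 11 of 20 cases (12 and 0 adjusted over the list alone, camera adjusted p = 2.77e-12, adjusted p = 0.000125 with an estimated correlation). Examples were irf9 (1.96 ± 0.13), irf1b (2.57 ± 0.22) and b2m (1.98 ± 0.18). Immediate early genes rose in 16 of 29 cases and fell in 2 (klf2b and klf2a). The counts became 17 and 3 adjusted over the list alone (camera adjusted p = 1.81e-18, adjusted p = 0.000998 with an estimated correlation). Apoptosis genes rose in 13 of 31 cases and fell in 2 (casp3a and cycsb). These were 15 and 3 adjusted over the list alone (camera adjusted p = 1.33e-05, adjusted p = 0.0303 with an estimated correlation). Among them were tnfrsf1a (1.63 ± 0.10), casp8 (1.05 ± 0.11) and bbc3 (1.27 ± 0.15). Steroid stress response genes rose in 12 of 27 cases and fell in 2 (cyp17a1 and pomca). The counts became 13 and 2 adjusted over the list alone (camera adjusted p = 3.15e-05, adjusted p = 0.0191 with an estimated correlation). Cardiac muscle genes rose in 8 of 18 (12 and 1 adjusted over the list alone, camera adjusted p = 0.000124, adjusted p = 0.0446 with an estimated correlation).

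Lower at 24 h in Meevs were members of several lists of tissue genes. Extracellular matrix and cartilage genes fell in 26 of 44 cases and rose in 3 (fn1b, fn1a and sox9b). These were 3 and 28 adjusted over the list alone (camera adjusted p = 1.44e-12, adjusted p = 0.0303 with an estimated correlation). Retina genes fell in 21 of 36 and rose in 2, rx1 among them (2 and 23 adjusted over the list alone, camera adjusted p = 1.83e-10, adjusted p = 0.0446 with an estimated correlation). Members included sagb (-2.01 ± 0.21), vsx1 (-0.82 ± 0.13) and rcvrna (-1.52 ± 0.24). Ionocyte and mucous cell markers fell in 12 of 21 cases and rose in 2 (ca15a and slc9a3.2). The counts became 2 and 16 adjusted over the list alone (camera adjusted p = 1.27e-07, adjusted p = 0.0303 with an estimated correlation). Neuronal differentiation genes fell in 26 of 44 cases (0 and 27 adjusted over the list alone, camera adjusted p = 4.29e-13, adjusted p = 0.177 with an estimated correlation). Such genes were tubb5 (-0.67 ± 0.06) and neurod6b (-1.17 ± 0.15). Mitochondrially encoded genes fell in 8 of 13 (0 and 8 adjusted over the list alone, camera adjusted p = 7.3e-05, adjusted p = 0.267 with an estimated correlation). Keratinocyte and periderm markers split, with a rise of krt18a.1 (1.56 ± 0.08) and falls of the basal cell genes col17a1a (-1.79 ± 0.12) and krtt1c19e (-1.75 ± 0.13). Of 47, 24 rose and 12 fell (28 and 13 adjusted over the list alone, camera adjusted p = 1.33e-05, adjusted p = 0.267 with an estimated correlation).

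Whether the genotypes differed in their response was tested as an interaction, the UVB effect in Meevs minus that in wild type. At 5 h the difference was positive for isg15 (2.34 ± 0.52, edgeR adjusted p = 0.00729), nfil3-6 (2.17 ± 0.33), ptgdsb.2 (2.16 ± 0.41), crtac1a (1.92 ± 0.29) and fosab (1.91 ± 0.33). It was negative for NPAS3 (-2.51 ± 0.49), clstn2 (-2.35 ± 0.42), ptprua (-2.30 ± 0.21) and klhl29 (-2.26 ± 0.29). The photolyase gene cry5 went from 5.2 ± 0.955 to 9.84 ± 1.37 CPM in wild type, and its rise was larger in Meevs by 1.64 ± 0.20 (edgeR adjusted p = 8.1e-06). Positive too were the differences of ddb2 (1.51 ± 0.18), phlda3 (1.19 ± 0.16) and gadd45aa (1.33 ± 0.19). Of 41 photolyase and clock genes 11 had a positive difference and none a negative one (14 and 1 adjusted over the list alone, camera adjusted p = 3.21e-10, adjusted p = 0.0026 with an estimated correlation). Examples were cry3b (1.03 ± 0.11), cry-dash (1.22 ± 0.13) and tefa (0.79 ± 0.09). In mock embryos at 5 h, 21 of the 41 list members were lower in Meevs and 4 higher. Between UVB embryos of the genotypes at 5 h the list's test did not pass.

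Over all genes the difference passed at 5 h for 452 genes in the positive and 691 in the negative direction, 84 and 129 of them at least 2-fold. Among the 472 genes over 200 kb the median difference was -0.50, and 150 of them, NPAS3 included, had a negative call. The split moved to 463 and 396 with gene length as an offset and to 246 and 837 without the 2 libraries at 5 h that stood apart on the principal components. It was 156 and 602 when only the 12 libraries at 5 h were fitted. Calls of the same direction in both genotypes at 5 h numbered 1220 higher and 1155 lower, against 283.7 and 207.1 for independent lists. Called in opposite directions were 3 genes, jakmip2, iqsec3b and znf1102. These contrasts share no library. Each series of libraries holds 1 genotype, so a difference between genotypes and a difference between series or exposure sessions cannot be told apart.

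At 24 h the difference was positive for the Polycomb gene cbx7a (3.45 ± 0.30, edgeR adjusted p = 4.42e-08), and for agxtb (3.01 ± 0.66). It was also positive for the complement genes c3a.3 (2.87 ± 0.36) and c7b (2.78 ± 0.76) and for isg15 (2.56 ± 0.39). The mock level of c3a.3 was lower in Meevs, 1.26 ± 0.558 against 7.5 ± 2.18 CPM in wild type, while the UVB levels were 60.2 ± 10.3 and 49.7 ± 10.8 CPM. The difference was negative for and3 (-2.74 ± 0.22), thbs4a (-2.04 ± 0.22), duox2 (-1.96 ± 0.47), and2 (-1.84 ± 0.19) and kera (-1.72 ± 0.15). In wild type and3 went from 108 ± 0.314 to 71.2 ± 7.90 CPM. Wound and fin regeneration genes had positive differences in 12 of 30 cases (15 and 0 adjusted over the list alone, camera adjusted p = 6.44e-23, adjusted p = 2.36e-05 with an estimated correlation). Among them were anxa2a (1.162 ± 0.10), krt18a.1 (1.08 ± 0.11) and junba (1.88 ± 0.20). Inflammation genes did so in 11 of 40 cases (20 and 1 adjusted over the list alone, camera adjusted p = 5.31e-23, adjusted p = 4.69e-05 with an estimated correlation). Members included socs3b (1.54 ± 0.13), stat3 (1.02 ± 0.14) and mmp9 (1.39 ± 0.20). Interferon-stimulated genes did so in 4 (irf9, irf7, b2m and isg15) of 20 (6 and 0 adjusted over the list alone, camera adjusted p = 1.03e-07, adjusted p = 0.0018 with an estimated correlation). Steroid stress response genes followed in 7 of 27 cases (8 and 2 adjusted over the list alone, camera adjusted p = 9.69e-07, adjusted p = 0.0079 with an estimated correlation). Such genes were igfbp1a (1.6 ± 0.19) and ddit4 (1.82 ± 0.24). Apoptosis genes did so in 4 (mcl1a, tnfrsf1a, casp8 and bbc3) of 31 (8 and 0 adjusted over the list alone, camera adjusted p = 2.33e-05, adjusted p = 0.0389 with an estimated correlation). Extracellular matrix and cartilage genes had negative differences in 9 of 44 cases and positive ones in 2 (fn1b and fn1a). These were 2 and 20 adjusted over the list alone (camera adjusted p = 1.52e-15, adjusted p = 0.0254 with an estimated correlation).

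In all 371 genes had a positive and 165 a negative difference at 24 h, 133 and 56 at least 2-fold. Calls shared by the genotypes numbered 345 higher and 98 lower, against 44.8 and 10 for independent lists. In opposite directions were 3 genes, slc6a11a, hspb9 and ENSDARG00000109310, whose symbol is a clone placeholder. The series confound stated for 5 h holds here too.

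**Figure D4:**
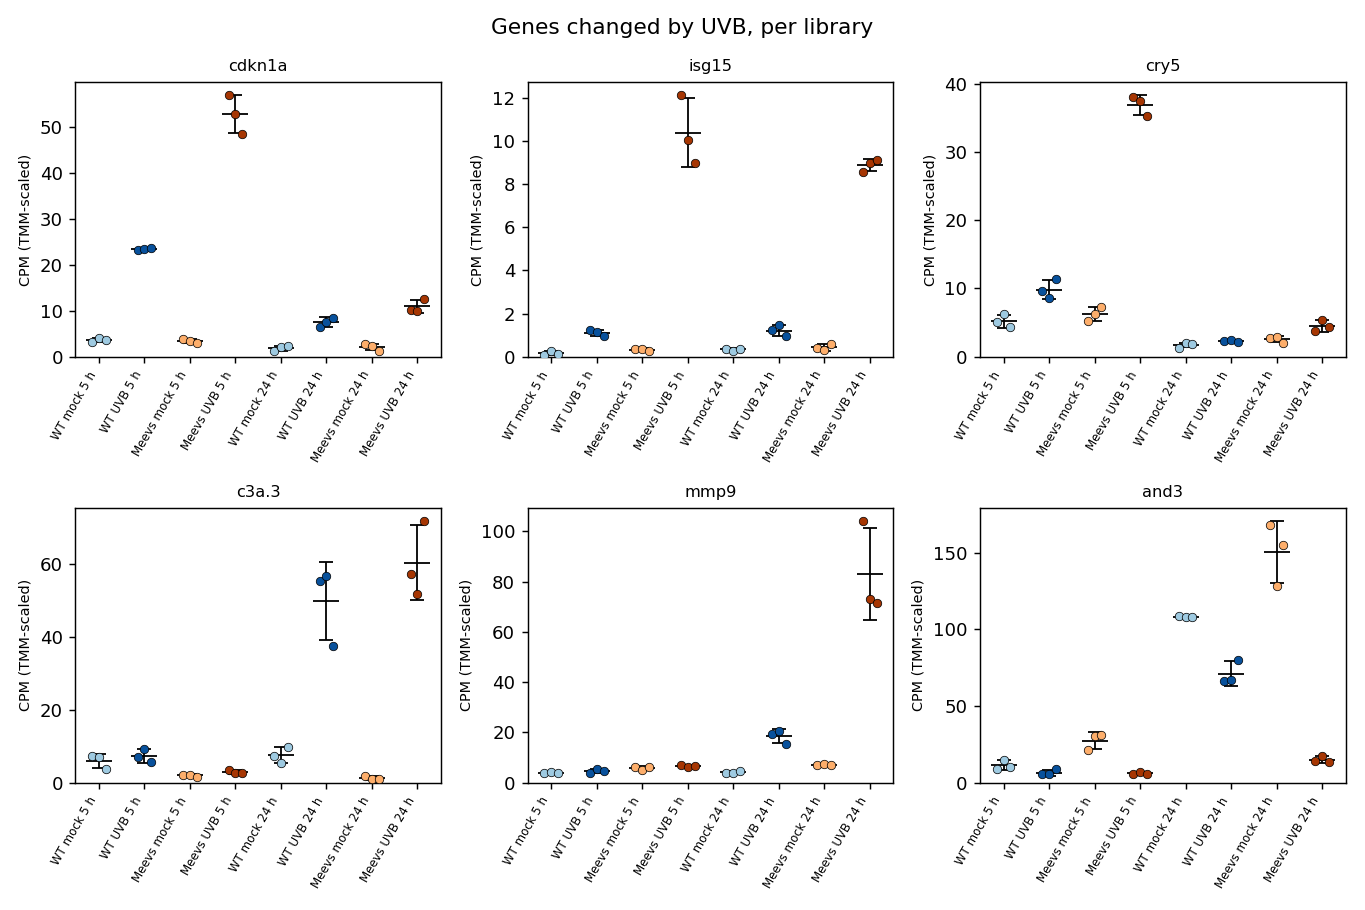
CPM of 6 genes (cdkn1a, isg15, cry5, c3a.3, mmp9 and and3) in each of the 24 libraries, with bars at group means and error bars of 1 SD (n = 3). Each panel has its own vertical scale from 0. UVB libraries of cdkn1a lie above mock libraries in each genotype and time, and and3 falls from a mean of 151 to 14.9 CPM in Meevs at 24 h.

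**Figure D5:**
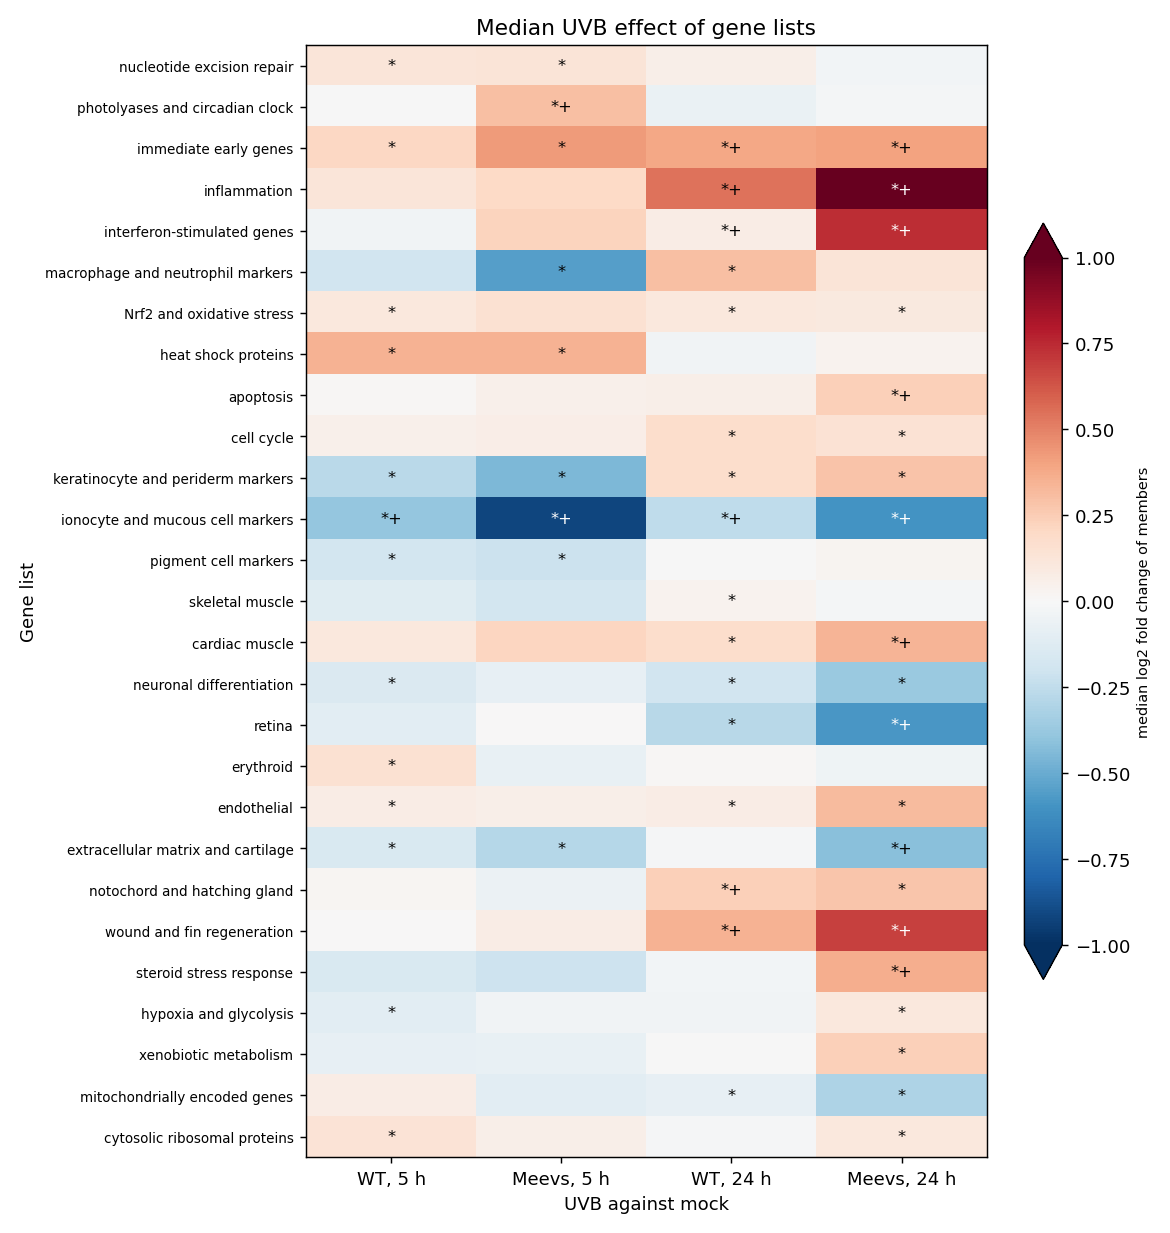
Median log2 fold change of the measured members of 27 gene lists with a camera call in at least 1 UVB effect (vertical axis) for UVB against mock in each genotype and time (horizontal axis), with colour from -1 (blue) to 1 (red) and values beyond drawn at the end colour. A star marks a camera adjusted p under 0.05 and a plus sign 1 that also held with an estimated correlation. Inflammation genes have the highest median, 1.356 in Meevs at 24 h, and ionocyte and mucous cell markers the lowest, -0.92 in Meevs at 5 h.

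The change of the UVB effect with time was tested within each genotype, the effect at 24 h minus that at 5 h. Hatching gland and complement genes were among those with the largest positive values in both. In wild type these were he1.3 (4.49 ± 0.50, edgeR adjusted p = 2.61e-06), c6 (2.5 ± 0.33), ctslb (2.5 ± 0.38), c3a.3 (2.48 ± 0.32) and fgfr1bl (2.35 ± 0.20), a symbol given to more than 1 identifier. In Meevs they were he1.3 (5.04 ± 0.48), c3a.3 (5.03 ± 0.48), c6 (4.13 ± 0.34), ctslb (3.98 ± 0.42) and mmp13a (3.95 ± 0.64). Among genes with a mean of at least 1 log2 CPM, the DNA damage gene gadd45aa was among the most negative in both, -2.04 ± 0.19 in wild type and -2.81 ± 0.18 in Meevs. The value of eevs, which is read at lower counts, was -5.24 ± 0.45 in Meevs. Also negative in wild type were apoa4b.2 (-1.49 ± 0.43), mylipb (-1.44 ± 0.38), trh (-1.26 ± 0.27) and hspb9 (-1.24 ± 0.32), of which apoa4b.2 has a shared symbol. In Meevs these were nfil3-6 (-2.69 ± 0.33), igfn1.3 (-2.47 ± 0.46), fosab (-2.37 ± 0.28) and lonrf1l (-2.2 ± 0.16).

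Keratinocyte and periderm markers had positive values in 23 of 47 cases in wild type (27 and 0 adjusted over the list alone, camera adjusted p = 2.82e-23, adjusted p = 0.0322 with an estimated correlation). In Meevs 29 were positive and 2 (krt5 and krtt1c19e) negative (32 and 2 adjusted over the list alone, camera adjusted p = 9.5e-20, adjusted p = 0.0442 with an estimated correlation). Examples were cldne (0.75 ± 0.10) and evpla (1.0 ± 0.14) in wild type and tgm1 (2.25 ± 0.16) in Meevs. Inflammation genes had positive values in 8 of 40 cases in wild type (11 and 0 adjusted over the list alone, camera adjusted p = 1.22e-07, adjusted p = 0.0259 with an estimated correlation). In Meevs 23 were positive (27 and 0 adjusted over the list alone, camera adjusted p = 9e-13, adjusted p = 0.00192 with an estimated correlation). Macrophage and neutrophil markers also had positive values, in 4 (mpx, nccrp1, mpeg1.2 and ptprc) of 25 cases in wild type (7 and 0 adjusted over the list alone, camera adjusted p = 0.00023, adjusted p = 0.258 with an estimated correlation). In Meevs 10 of these were positive (10 and 0 adjusted over the list alone, camera adjusted p = 0.000768, adjusted p = 0.223 with an estimated correlation). The list had fallen in Meevs at 5 h, and its UVB effect there at 24 h did not pass. At 24 h 6 members rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.0646, adjusted p = 0.481 with an estimated correlation). Wound and fin regeneration genes had positive values in 5 (anxa2a, fn1b, mmp9, timp2b and mmp13b) of 30 in wild type (8 and 0 adjusted over the list alone, camera adjusted p = 1.22e-07, adjusted p = 0.0171 with an estimated correlation). In Meevs 14 of these were positive (16 and 0 adjusted over the list alone, camera adjusted p = 9e-13, adjusted p = 0.000865 with an estimated correlation). In Meevs photolyase and clock genes had negative values in 14 of 41 cases and positive ones in 4 (bhlhe40, cry4, per1b and rorcb). The counts became 4 and 14 adjusted over the list alone (camera adjusted p = 2.1e-05, adjusted p = 0.0395 with an estimated correlation). Examples were cry3b (-1.89 ± 0.11) and per2 (-1.71 ± 0.16).

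In wild type 729 genes had a positive and 363 a negative value, 183 and 34 at least 2-fold. The split moved to 808 and 703 in DESeq2 and to 592 and 456 with the length offset. This total of 1092 became 687 without wild type UVB replicate 1 at 5 h and 675 without wild type mock replicate 2 at 24 h. It became 1775 (907 and 868) without the 2 libraries at 5 h that stood apart on the principal components, an alternative chosen after seeing the data. In Meevs 3365 genes had a positive and 3205 a negative value, 1162 and 384 at least 2-fold. The larger share turned negative with DESeq2 size factors in edgeR (3165 and 3564), in DESeq2 (3210 and 3675) and with the length offset (2784 and 3707).

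Without UVB, the genotypes were compared in mock embryos to describe the starting state of the mutant. Lens crystallin genes of 1 tandem family, whose reads could be shared between copies, were among the largest positive values at 5 h, crygm2d14 (2.11 ± 0.47), crygm2d4 (1.82 ± 0.32), crygm2d18 (1.77 ± 0.29), crygm2d2 (1.73 ± 0.31) and crygm2d13 (1.71 ± 0.26). They were joined by thy1 (1.92 ± 0.16), thbs4a (1.86 ± 0.18), cldn11a (1.71 ± 0.20), ponzr3 (1.68 ± 0.45) and ybey (1.68 ± 0.19). The largest negative values were in ggact.3 (-4.55 ± 0.58, edgeR adjusted p = 6.09e-07) and ggact.2 (-4.35 ± 0.62), gamma-glutamylamine cyclotransferase genes. These were read in 1 of 3 Meevs mock libraries at 5 h with at most 12 and 23 counts. They were followed by the actin gene actc1a (-4.11 ± 0.94) and by onecut2 (-3.02 ± 0.39), ctbs (-2.95 ± 0.39), ago1 (-2.78 ± 0.19), lcor (-2.72 ± 0.30), fam168a (-2.48 ± 0.17), vdrb (-2.26 ± 0.24) and lin28b (-2.26 ± 0.21). The symbols ybey and actc1a are given to more than 1 identifier, whose values went opposite ways. Named here and for UVB embryos is the actc1a of ENSDARG00000076126, at 31.80 ± 18.04 CPM in wild type and 1.85 ± 0.330 CPM in Meevs mock embryos at 5 h. The more abundant ENSDARG00000042535 was higher in Meevs, at 884 ± 26.3 and 1321 ± 140 CPM (0.58 ± 0.14). The ybey named is ENSDARG00000011999, and ENSDARG00000110510 was lower in Meevs at 24 h (-0.76 ± 0.19). At 24 h the ammonium transporter gene rhcga (3.33 ± 0.76), cyp24a1 (2.58 ± 0.21) and agxtb (2.21 ± 0.45) had the largest positive values. Next were ybey (1.94 ± 0.21), thy1 (1.74 ± 0.16), ponzr3 (1.62 ± 0.27), mustn1a (1.57 ± 0.28), pigbos1 (1.57 ± 0.14), rrm2 (1.53 ± 0.23) and f7i (1.51 ± 0.15). The negative side held ggact.3 (-2.82 ± 0.51), mxra5b (-2.71 ± 0.31), ggact.2 (-2.7 ± 0.51), ago1 (-2.64 ± 0.20) and lcor (-2.63 ± 0.20), then MAP3K13 (-2.61 ± 0.23), c3a.3 (-2.59 ± 0.30), fam168a (-2.48 ± 0.15), ctbs (-2.41 ± 0.42) and prtgb (-2.36 ± 0.30).

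Differences between mock genotypes numbered 5480 positive and 5185 negative at 5 h (471 and 1109 at least 2-fold), and 5923 and 5848 at 24 h (575 and 1267). Cytosolic ribosomal protein genes were higher in Meevs in 78 of 79 cases at 5 h (78 and 0 adjusted over the list alone, camera adjusted p = 6.46e-38, adjusted p = 0.763 with an estimated correlation). At 24 h 76 were higher (77 and 0 adjusted over the list alone, camera adjusted p = 2.18e-34, adjusted p = 0.781 with an estimated correlation). The difference of rpl36 was 1.03 ± 0.10 and 1.15 ± 0.10. Photolyase and clock genes were lower in Meevs in 21 of 41 cases at 5 h, per3 (-1.0 ± 0.11) and arntl2 (-0.81 ± 0.10) among them, and higher in 4 (bhlhe40, cry4, cry3b and cpdp). These were 5 and 21 adjusted over the list alone (camera adjusted p = 0.0208, adjusted p = 0.763 with an estimated correlation). At 24 h 6 were higher and 18 lower (6 and 18 adjusted over the list alone). The list's test did not pass then (camera adjusted p = 0.096, adjusted p = 0.781 with an estimated correlation). In UVB embryos at 5 h 14 were higher and 10 lower, and the list's test did not pass (14 and 10 adjusted over the list alone, camera adjusted p = 0.203, adjusted p = 0.783 with an estimated correlation). The log2 difference between genotypes moved with gene span, with Spearman correlations across genes of -0.353 and -0.414 in mock and -0.456 and -0.384 in UVB embryos at 5 h and 24 h. Genotype coincides with library series throughout, and no list held with an estimated correlation in mock embryos. The lists were not tested with gene length as an offset, so the part of gene span in their genotype differences is not known.

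Among UVB embryos the genotypes differed at 5 h by 6098 positive and 5140 negative genes (639 and 1122 at least 2-fold). The highest were lgsn (3.66 ± 1.1), crtac1a (3.25 ± 0.17), isg15 (3.24 ± 0.18), crygm2d16 (2.74 ± 0.64) and crygm2d14 (2.52 ± 0.42). Among the lowest were clstn2 (-3.23 ± 0.32), slc16a6a (-3.00 ± 0.78), ctbs (-2.97 ± 0.34) and ptprua (-2.66 ± 0.16). At 24 h the counts were 6366 and 6110 (1035 and 1317). Highest then were rhcga (5.27 ± 0.52), agxtb (5.21 ± 0.38), cbx7a (3.55 ± 0.18), c7b (3.33 ± 0.39) and hspb11 (3.22 ± 0.22), and lowest ggact.2 (-3.59 ± 0.54), actc1a (-3.57 ± 0.99), ggact.3 (-3.52 ± 0.54), crestin (-2.56 ± 0.36) and onecut2 (-2.47 ± 0.33). Wound and fin regeneration genes were then higher in Meevs in 23 of 30 cases and lower in 2 (wnt10a and sox11b). The counts became 23 and 2 adjusted over the list alone (camera adjusted p = 4.84e-12, adjusted p = 0.00099 with an estimated correlation). Inflammation genes were higher in 30 of 40 and lower in 4 (tnip1, tnfaip3, nos2b and rela). These were 31 and 5 adjusted over the list alone (camera adjusted p = 8.95e-11, adjusted p = 0.00257 with an estimated correlation). Interferon-stimulated genes were higher in 12 of 20 and lower in 1 (eif2ak2). The counts became 13 and 1 adjusted over the list alone (camera adjusted p = 0.000415, adjusted p = 0.0493 with an estimated correlation).

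Development between 29 and 48 hpf in mock embryos gave the size of change with age, from which clutch and collection were not separated. The opsin gene rho was read at 0 to 2 counts per library at 29 hpf in both genotypes and at 6.97 ± 0.882 CPM in wild type and 8.49 ± 1.72 CPM in Meevs at 48 hpf. The cartilage collagen gene col10a1a went from 0 to 3 counts per library to 28.9 ± 4.04 and 46.9 ± 6.22 CPM. The muscle gene ampd1 and the photoreceptor gene six7 rose by 8.86 ± 0.29 and 8.18 ± 0.28 in wild type and by 8.19 ± 0.28 and 7.65 ± 0.29 in Meevs (edgeR adjusted p = 1.54e-18, 2.2e-18, 3.07e-18 and 2.93e-17). Crystallin genes of the tandem family, crygm2d15 in wild type and crygm2d11 in Meevs, completed the 5 largest rises. Falling were the hatching gland genes he1.3 (-7.83 ± 0.33 and -6.61 ± 0.36) and ctslb (-5.95 ± 0.29 and -6.72 ± 0.32 in wild type and Meevs). So were prtgb (-5.42 ± 0.18 and -5.56 ± 0.24) and cyp4t8 (-4.96 ± 0.14 and -4.88 ± 0.13), METTL21C in wild type (-5.13 ± 0.23) and wfikkn1 in Meevs (-4.72 ± 0.19). Neuronal differentiation genes rose in 43 of 44 cases in wild type (43 and 0 adjusted over the list alone, camera adjusted p = 7.04e-40, adjusted p = 0.111 with an estimated correlation). In Meevs 43 of them rose (43 and 0 adjusted over the list alone, camera adjusted p = 7.04e-39, adjusted p = 0.102 with an estimated correlation). Cell cycle genes fell in 53 of 55 cases in wild type (0 and 53 adjusted over the list alone, camera adjusted p = 1.4e-21, adjusted p = 0.244 with an estimated correlation). In Meevs 53 of them fell (0 and 53 adjusted over the list alone, camera adjusted p = 1.64e-23, adjusted p = 0.191 with an estimated correlation). In wild type 6749 genes rose and 7490 fell, 3628 and 1665 at least 2-fold, and in Meevs 6405 and 7039, 3462 and 1430 at least 2-fold.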

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

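The tests of lesions, of library series, of exchanged treatment labels and of counting noise, the thinning of libraries, the length offset and the make-up of the splits were chosen only after the results were seen.

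The UVB effect differed between genotypes, by an edgeR test of the difference itself, for 1143 genes at 5 h and for 536 at 24 h. The 5 h values, Meevs minus wild type, included isg15 (2.34 ± 0.52), nfil3-6 (2.17 ± 0.33), ptgdsb.2 (2.16 ± 0.41), crtac1a (1.92 ± 0.29) and fosab (1.91 ± 0.33) on the positive side and NPAS3 (-2.51 ± 0.49), clstn2 (-2.35 ± 0.42), ptprua (-2.30 ± 0.21) and klhl29 (-2.26 ± 0.29) on the negative. The 24 h values were cbx7a (3.45 ± 0.30), agxtb (3.01 ± 0.66), c3a.3 (2.87 ± 0.36), c7b (2.78 ± 0.76) and isg15 (2.56 ± 0.39), and and3 (-2.74 ± 0.22), thbs4a (-2.04 ± 0.22), duox2 (-1.96 ± 0.47), and2 (-1.84 ± 0.19) and kera (-1.72 ± 0.15). The UVB effect differed between 5 h and 24 h for 1092 genes in wild type and 6570 in Meevs. In wild type the values, 24 h minus 5 h, were he1.3 (4.49 ± 0.50), c6 (2.5 ± 0.33), ctslb (2.5 ± 0.38), c3a.3 (2.48 ± 0.32) and fgfr1bl (2.35 ± 0.20) and gadd45aa (-2.04 ± 0.19), apoa4b.2 (-1.49 ± 0.43), mylipb (-1.44 ± 0.38), trh (-1.26 ± 0.27) and hspb9 (-1.24 ± 0.32). In Meevs they were he1.3 (5.04 ± 0.48), c3a.3 (5.03 ± 0.48), c6 (4.13 ± 0.34), ctslb (3.98 ± 0.42) and mmp13a (3.95 ± 0.64) and gadd45aa (-2.81 ± 0.18), nfil3-6 (-2.69 ± 0.33), igfn1.3 (-2.47 ± 0.46), fosab (-2.37 ± 0.28) and lonrf1l (-2.2 ± 0.16).

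Other splits of the same libraries were fitted without the remaining groups. The genotype-by-UVB difference at 5 h then called 758 genes. As many were called by 9 of 100 splits, the real one included, with 7501 as the highest other count. At 24 h it called 579 genes, again matched by 9 of 100 splits, with 5071 as the highest other. Chance was not excluded by this count at either time. Each of the 8 other splits as large kept treatment whole within Meevs. Counts several times the real one point to that structure of the samples, the UVB effect in Meevs. The 83 splits that mixed treatment in both genotypes called 0 genes in edgeR at either time. For the UVB effect by time the share of splits was under 0.05, which does not by itself exclude chance. The 83 splits that mixed treatment at both times called at most 13 genes in wild type and 0 in Meevs. Few of the drawn splits could thus reach the real count. In wild type 1010 genes were called and 2 of 100 splits gave as many (highest other 1928, a split that kept treatment whole at 5 h). In Meevs 6078 were called and 1 of 100, the real one, gave as many (highest other 2336).

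Comparisons of 3 libraries with 3 have 10 splits, too few for a share under 0.05. The real split, 1 of 10 in each case, called 1768 genes for the UVB effect in wild type at 5 h (highest other 1), and the highest other was 0 for the rest. The real counts were 595 in wild type at 24 h, 6427 and 4029 in Meevs at 5 h and 24 h, and 9025 and 12367 for genotype in mock embryos. They were 10851 and 11893 for genotype in UVB embryos, and 14141 and 12343 for time in wild type and Meevs.

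Long genes were lower 5 h after UVB: the median log2 level of genes over 200 kb minus that of genes up to 50 kb fell by 0.901 in Meevs and fell by 0.37 in wild type. A length bias that varies between libraries by chance was argued against by a 2-sided exact permutation p of 0.005 over treatment within genotype, the smallest that 400 splits can give. With the lag predicted from the other genotype's time effect removed, the Meevs difference was -0.849. This argues only against a lag that follows the change in mock embryos between the collection times. Embryos that lag at 5 h would resemble stages before the 5 h collection, which were not sampled. Neither this value nor the genes with little change over time can test such a lag, so it stays open. Among genes with little change over time the median UVB effect fell with every longer class in both genotypes, to -0.838 for the longest class in Meevs. Any cause linked to length would give this trend. UVB lesions that stop RNA polymerase more often in longer genes, a loss of RNA integrity and a length bias tied to the exposed embryos therefore all stay open, and no transcript lengths or RNA quality values were used here.

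The UVB response held more genes in Meevs, 2.7 times the wild type calls at 5 h and 9.09 times at 24 h. Sequencing depth was argued against by thinning all libraries to 22395870 counts, after which the ratios were 2.79 and 10.6. The size of the ratios depends on single wild type libraries. At 5 h the wild type count of 2842 became 1781 without mock replicate 3 and 1385 without UVB replicate 1. At 24 h the count of 501 became 273 without mock replicate 1, 333 without mock replicate 3, 293 without UVB replicate 2 and 313 without UVB replicate 3. Over all fits that left out 1 library, wild type counts reached at most 3425 and 748, and Meevs counts were at least 6122 and 3439. Fits of the compared groups only called 1768 and 595 genes in wild type and 6427 and 4029 in Meevs. Over genes called in wild type at 24 h, the slope of the Meevs on the wild type fold change was 1.363, against 1.07 at 5 h. A loss of the maternal sunscreen in Meevs may enlarge the response, but each library series holds 1 genotype, so genotype, series and exposure session cannot be told apart.

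The counts of eevs in Meevs were high in UVB embryos at 5 h and in mock embryos at 24 h and low in the other 2 groups. Counting noise at low counts is argued against by the ratios of the summed counts, whose lower 95% Poisson bounds were 5.96 at 5 h and 2.62 at 24 h. To check for exchanged genotype labels, 38 marker genes were chosen in the other groups. At least 84.2% of them lay on the Meevs side in each of the 6 Meevs libraries with low eevs. This argues against libraries exchanged between the 2 series. The markers may mark the series as well as the genotype, so they cannot decide whether embryos were mislabelled before. Exchanged treatment labels at 24 h are argued against by 98% of the genes called in wild type, which changed in the same direction in Meevs. A difference in the embryos' own eevs alleles between the clutches stays possible and untested, since the labels do not give the alleles.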

How the results depend on the processing

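The length offset, the 2 apart libraries at 5 h left out together and the thinning are tests chosen only after the results were seen; all other alternatives were planned.

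Every count of calls stayed within 1.5 times its value under DESeq2 size factors, the DESeq2 Wald test, no filter, the length offset and the thinning (run for the UVB effects: 2608 and 414 in wild type, 7287 and 4378 in Meevs, at 5 h and 24 h). Fitting the compared groups only moved 2 of 14 counts, from 2842 to 1768 for the UVB effect in wild type at 5 h and from 1143 to 758 for genotype by UVB at 5 h. This fit has fewer samples to estimate the spread. Without wild type UVB replicate 3 and Meevs mock replicate 3 at 5 h, the count for UVB by time in wild type went from 1092 to 1775. The other 7 counts that use these groups stayed within 1.5 times. The 2 libraries at 24 h that stood apart were left out one at a time only, which gave 748 genes for wild type at 24 h without UVB replicate 1 and 4394 for Meevs at 24 h without UVB replicate 3. Without the 2 apart libraries at 5 h, the split for Meevs at 5 h went from 4256 higher and 3419 lower to 2981 and 3591. For genotype by UVB at 5 h it went from 452 and 691 to 246 and 837; the cause was not tested.

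The direction of the larger share of calls depended on the setting in several contrasts. With DESeq2 size factors it turned for the UVB effect in wild type at 5 h (1372 higher and 1426 lower) and in Meevs at 24 h (2353 and 2395), for UVB by time in Meevs (3165 and 3564) and for time in Meevs (6702 and 6644). The DESeq2 Wald test turned the same 4. Fitting the compared groups only turned it for the UVB effects at 5 h (754 and 1014 in wild type, 2963 and 3464 in Meevs), for genotype in mock embryos at both times and in UVB embryos at 5 h, and for time in both genotypes. The replicate block turned the latter 5. For these contrasts the block was fitted to the compared libraries only, so its own part in the turn cannot be told. The length offset turned it for UVB in Meevs at 24 h (2472 and 2555), genotype by UVB at 5 h (463 and 396) and UVB by time in Meevs (2784 and 3707). Leaving out the 2 apart libraries at 5 h turned it for UVB in Meevs at 5 h, genotype in UVB embryos at 5 h (4906 and 5337) and time in Meevs (6420 and 6253). The cause was not tested.

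Leaving out each replicate in turn gave 1385 to 3425 genes for UVB in wild type at 5 h and 273 to 748 at 24 h. In Meevs it gave 6122 to 7027 and 3439 to 4394. It gave 787 to 1236 for genotype by UVB at 5 h, 358 to 473 at 24 h, 675 to 1434 for UVB by time in wild type and 5718 to 6317 in Meevs. Outside 1.5 times were wild type counts without mock replicate 3 (1781) or UVB replicate 1 (1385) at 5 h. At 24 h they were those without mock replicate 1 (273), mock replicate 3 (333), UVB replicate 2 (293) or UVB replicate 3 (313), and for UVB by time those without UVB replicate 1 at 5 h (687) or mock replicate 2 at 24 h (675). The genotype effects ranged over 8660 to 10199 and 10251 to 11022 in mock and 9722 to 10616 and 10958 to 12092 in UVB embryos. The time effects ranged over 13039 to 13555 and 12362 to 12641. All these fits have 1 sample fewer; no other cause was tested.

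With a replicate block the counts were 2843, 469, 7530 and 4486 for the UVB effects, 1036 and 502 for genotype by UVB and 963 and 6470 for UVB by time. None of the 14 moved by over 1.5 times. The replicate numbers showed no clear pairing of the samples. Correlations of the deviations of equal numbers ran from -0.08 to 0.11, 1 of 12 was over 0.1, and 5 of 12 libraries correlated best with their own number. In wild type at 24 h each library did so (0.11, 0.06 and 0.07), and in Meevs at 5 h no library did, so a pairing in single groups is not excluded. The block ended 3 of 125 list calls run with it, all in the genotype-by-UVB differences. They were unfolded protein and amino acid response genes at 5 h (camera adjusted p = 0.0515) and nucleotide excision repair genes (0.0568) and keratinocyte and periderm markers (0.0608) at 24 h.

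Of the calls of named genes, DESeq2 ended 12 of 1636, RLE 11 of 1643, no filter 7, the block 39, the compared groups alone 60, the 2 apart libraries at 5 h left out 37 of 937, the thinning 19 of 435 and leaving out replicates 753 of 11802. The length offset ended 59 and reversed 9. These were rbfox3a (0.052 in wild type and 0.468 in Meevs at 5 h after UVB), rbfox1 (0.124 and 0.377), and flt4 (0.084) and lamc1 (0.036) in Meevs at 5 h. The others were zbtb16a (0.084) and foxp1b (0.22) between genotypes in UVB embryos at 5 h, and foxp1b (-0.13) with time in wild type. Only rbfox1 and rbfox3a in Meevs at 5 h passed in the new direction (edgeR adjusted p = 0.00102 and 0.000382). The remaining reversed values did not pass. Leaving out replicates ended 130 of 1554 list calls. Among lists, keratinocyte and periderm markers in genotype by UVB at 24 h reversed without Meevs UVB replicate 2. The signed -log10 camera p went from 1.824 to -0.08882 and ranged up to 3.683, and the cause was not tested.

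Depth limits the genes read at few counts: eevs had 2 to 84 counts per library, and he1.3, rho, ggact.2 and ggact.3 had near 0 in some groups, so that their fold changes are less certain than their levels. In simulated counts, 74% of 1.5-fold UVB effects in wild type at 5 h and 42% of genotype-by-UVB differences of that size were recovered. The simulated changes were placed only in genes of higher mean counts, so these shares do not cover genes read at few counts.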

Other observations

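The tests of a developmental lag and of the neighbourhood of eevs were chosen only after the results were seen.

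In Meevs at 24 h, of 28 heat shock genes 7 rose and 2 (serpinh1b and dnaja1) fell, and the list's test did not pass (9 and 2 adjusted over the list alone, camera adjusted p = 0.151, adjusted p = 0.719 with an estimated correlation). Among those that rose were hspb11 (2.43 ± 0.21), hspb1 (1.29 ± 0.12) and bag3, a partner of HSP70 chaperones (0.81 ± 0.10). The difference from wild type passed for 4 of 28 heat shock genes, hspb11 (2.51 ± 0.33), hspb9 (2.16 ± 0.31), hspb1 (1.14 ± 0.17) and bag3 (0.69 ± 0.14). The counts became 4 and 0 adjusted over the list alone (camera adjusted p = 0.00167, adjusted p = 0.44 with an estimated correlation). Nrf2 and oxidative stress genes rose in 16 of 40 cases and fell in 3 (nqo1, me1 and sod3a). These were 16 and 5 adjusted over the list alone (camera adjusted p = 0.000472, adjusted p = 0.267 with an estimated correlation). Among them were the autophagy receptor gene sqstm1 (1.22 ± 0.09) and gpx1b (1.11 ± 0.15). Hypoxia and glycolysis genes rose in 12 of 38 cases and fell in 2 (slc2a1a and pkmb). The counts became 13 and 2 adjusted over the list alone (camera adjusted p = 0.000339, adjusted p = 0.267 with an estimated correlation). Members included igfbp1a (2.35 ± 0.13), pfkfb3 (1.15 ± 0.14) and gapdh (0.78 ± 0.10). Endothelial genes rose in 12 of 30 cases and fell in 1 (tal1). These were 15 and 1 adjusted over the list alone (camera adjusted p = 6.56e-06, adjusted p = 0.133 with an estimated correlation). Such genes were the scavenger receptors stab2 (1.06 ± 0.10) and stab1 (1.19 ± 0.14). Liver and yolk lipoprotein genes went both ways, 13 of 44 rising and 12 falling (14 and 13 adjusted over the list alone, camera adjusted p = 0.12, adjusted p = 0.847 with an estimated correlation). The complement genes cfb (2.51 ± 0.14) and c3a.1 (2.18 ± 0.15) and the fibrinogen gene fgb (1.35 ± 0.12) rose, and the retinol carrier gene rbp4 (-1.17 ± 0.10) fell.

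At 5 h in Meevs, of 34 unfolded protein and amino acid response genes 13 fell and 5 (asns, ddit4, cebpb, ddit3 and mthfd2) rose, and the list's test did not pass (6 and 13 adjusted over the list alone, camera adjusted p = 0.155, adjusted p = 0.725 with an estimated correlation). Among those that fell were hsp90b1 (-0.67 ± 0.06), calr3b (-0.58 ± 0.08) and edem1 (-0.51 ± 0.08). Pigment cell markers fell in 13 of 33 cases and rose in 1 (gmps). The counts became 1 and 13 adjusted over the list alone (camera adjusted p = 0.00105, adjusted p = 0.553 with an estimated correlation). Examples were trpm1b (-0.82 ± 0.08) and the xanthophore genes aox5 (-0.69 ± 0.08) and gch2 (-0.65 ± 0.10). In mock embryos lens crystallins were higher in Meevs in 15 of 26 cases at 5 h (15 and 0 adjusted over the list alone, camera adjusted p = 0.000262, adjusted p = 0.816 with an estimated correlation). At 24 h 10 of 26 were higher (10 and 0 adjusted over the list alone). The list's test did not pass then (camera adjusted p = 0.096, adjusted p = 0.899 with an estimated correlation).

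A developmental lag of exposed embryos is a hypothesis. Across genes, which are not independent replicates, the UVB effect sloped against the time effect of the other genotype's mock embryos, by -0.084 and -0.103 in wild type and -0.077 and -0.15 in Meevs at 5 h and 24 h. A score of each library along the time effect was lower in UVB than in mock libraries by a mean of -0.097 of the change between 29 and 48 hpf. The 2-sided exact permutation p within genotype and time was 1.25e-05, the smallest that 160000 splits can give, and the difference was negative in each of the 4 sets (-0.078 and -0.1 in wild type, -0.068 and -0.141 in Meevs). UVB-exposed embryos may thus lag in developmental expression, and damage to late-forming tissues could give the same score. The time effect in mock embryos rose with gene span (Spearman's correlation across genes 0.151 in wild type and 0.109 in Meevs), while the UVB effect fell with it. The fall of long genes after UVB could therefore lower the score too, and the score was not tested with the length offset.

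Whether differences between the lines cluster near eevs could not be told. Of 198 genes within 5 Mb of it, 58.6% were called between mock genotypes at 24 h against 52.6% elsewhere (2-sided Fisher's exact p = 0.1). At 5 h the shares were 54.0% against 47.7% (exact p = 0.0861). Of calls of at least 2-fold the shares were 10.1% near eevs against 8.23% elsewhere at 24 h (exact p = 0.362) and 6.57% against 7.08% at 5 h (exact p = 0.89).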
